A study of Penaeus vannamei with 6 samples.

How the data were processed

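Gill RNA of juvenile whiteleg shrimp (Penaeus vannamei, also called Litopenaeus vannamei) cultured in seawater, brackish water or fresh water was sequenced from mRNA libraries. The study's design text speaks of 3 libraries per condition, and 2 libraries of each condition, 6 in all, were analysed here. Groups and library numbers were taken from the submitters' labels. Nothing in the labels says that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

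Per the file headers, the authors deposited RPKM values, that is reads per kilobase of transcript, scaled to the total reads of the library, for each library and each of 341828 assembled transcripts. The study's title names a de novo assembly, and the assembler, aligner, counting tool and their versions are not given in the sources used here. Per the file headers, the authors also deposited the mean read count of each group, an estimated count averaged over 2 libraries, in the tables that set brackish water and fresh water against seawater. The same tables hold the authors' log2 fold change of mean RPKM, in which a mean of 0 stands as 0.01 in the values, and the authors' p-value. In these 2 tables the authors' yes or no mark of significance equalled an unadjusted p-value under 0.05 with a log2 fold change past 1 in size, with 0 exceptions. Within 1e-04, 96.7% of the deposited p-values for brackish water and 99.6% of those for fresh water equalled an equal-variance t-test on RPKM, and 100% of those for the 3 groups equalled a one-way analysis of variance. The authors' deposited table of all transcripts holds further marks under FDR headers, whose rule is not given in the sources used here. The authors' deposited table of fresh water against seawater listed 55575 transcripts, with a highest p-value of 0.0500. In the table of all transcripts, 1 cell of the fresh against brackish water mark held a number and was not used here.

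The RPKM values kept the whole reads behind them. RPKM multiplied by transcript length was a whole multiple of 1 step per library, within 0.1 read, for 100% of the values above 0 in 5 libraries and for 99.997% in brackish water library 2. The multiples were taken as reads, and their averages equalled 100% of the deposited mean counts. Their sums gave depths of 16500257 and 33130083 reads in seawater, 37027007 and 35347475 in brackish water, and 30152208 and 23195528 in fresh water. A transcript of 1 kilobase with 1 read stood at 0.0606 RPKM in the shallowest library and at 0.0270 in the deepest. Replicate libraries were compared by a chi-square of reads over transcripts with at least 20 reads in the pair, which came to 345 per transcript in seawater, 471 in brackish water and 49.2 in fresh water, so no library was counted as a duplicate of another.

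Before the data were examined, the groups, the tests, the alternatives listed first below and the rule for naming transcripts were set. The plan held a branch for read counts and a branch for normalized values. The first named the edgeR quasi-likelihood test with TMM and filterByExpr defaults. Because the libraries were deposited as RPKM, the second was used. Transcripts with a mean of at least 1 RPKM over the 6 libraries, 25901 in number, were tested with limma 3.58.1 with a trend on log2(RPKM + 1). All 6 libraries entered one fit with group as the only term and 3 residual degrees of freedom, and Benjamini-Hochberg adjustment was applied with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of transcripts of low RPKM. The 3 pairs of groups and an F test of the 3 groups were computed.

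The files pair the transcript IDs with no gene name or description, and 0 IDs matched the RefSeq gene table of assembly ASM4276789v1. The lists of ion pumps, transporters, aquaporins, osmolyte and stress genes and of markers of other cell types that had been set beforehand could therefore not be applied. By the naming rule for that case, at most 2 transcripts that rose and 2 that fell were named for each comparison with seawater. These were the largest changes among called transcripts with a mean of at least 5 RPKM whose groups did not overlap. Transcripts of one assembly component share sequence, so reads may be split between them.

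Alternatives set beforehand were quantile normalization, other filters and pseudocounts, a replicate block, fits of the compared groups alone, sums per assembly component and each library left out in turn. Alternatives chosen after seeing the data were RPKM divided by TMM factors, edgeR 4.0.16 quasi-likelihood tests on the recovered reads with TMM or with DESeq2 size factors, and DESeq2 1.42.0 on the recovered reads. The edgeR test with TMM is the one planned for deposited read counts. Only its use on recovered reads was chosen afterwards. Also chosen after seeing the data were fits of RPKM and of TMM-scaled RPKM with the prior degrees of freedom of limma exchanged, and fold changes with 1 seawater library for each comparison. The edgeR fits used filterByExpr defaults and kept 43835 transcripts. R 4.3.3 was used for the fits and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for the rest.

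The fits were tested on simulated reads for fresh water against seawater over 25804 transcripts, with 100 transcripts changed 4-fold and 100 changed 16-fold. With a biological coefficient of variation of 0.2, limma recovered 89% of the 4-fold and 98% of the 16-fold changes and edgeR recovered 90% and 100%, with 17 and 12 unchanged transcripts called. With the dispersions of the real libraries, both recovered 0 of 100 at either size and called 0 unchanged transcripts. Since limma called 951 transcripts in the real libraries, this last simulation does not measure the sensitivity of that fit. For edgeR it means that 0 calls can be due even where such changes are present. The sensitivity of limma diffSplice was measured by changing the fresh water values of 2 transcripts in 183 of 3654 components, in 20 draws for each size of change. Shared seawater controls were simulated in 100 draws of unchanged groups.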

Results

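Transcript levels were measured in the gill, the organ of ion exchange in shrimp, in 2 seawater, 2 brackish water and 2 fresh water libraries of juvenile Penaeus vannamei. The study asked how the gill transcriptome differs between the culture salinities. Depth ran from 16500257 reads in seawater library 1 to 37027007 in brackish water library 1. The assembly held 341828 transcripts in 321483 components, with a median length of 259 bases, and 32420 transcripts had no read in any of the 6 libraries.

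The number of transcripts with reads differed between libraries more than depth did. Seawater libraries 1 and 2 held reads for 55464 and 72650 transcripts, and fresh water libraries 1 and 2 for 207274 and 213853. The brackish water libraries differed from each other, with 203824 transcripts in library 1 and 61478 in library 2. With every library thinned to 16500257 reads, the expected numbers were 55464 and 61556 in seawater, 157647 and 51304 in brackish water, and 171595 and 193881 in fresh water. Brackish water library 2 was also the most uneven, with 41.2% of its reads in its 10 most abundant transcripts against 9.63% to 16.3% in the other libraries.

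**Figure D1:**
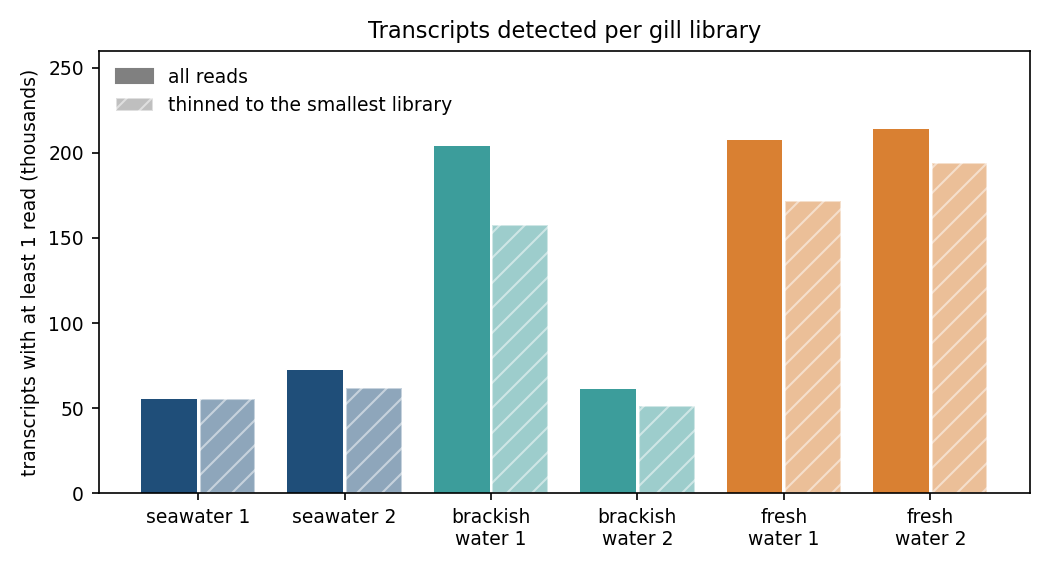
Transcripts with at least 1 read, in units of 1000 transcripts, for each of the 6 libraries, from all reads (solid bars) and after thinning to 16500257 reads (hatched bars). Brackish water library 1 stands near the fresh water libraries and brackish water library 2 near the seawater libraries.

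Across the 25901 tested transcripts, Pearson's r of log2(RPKM + 1) was 0.942 between the fresh water libraries, 0.819 between the seawater libraries and 0.722 between the brackish water libraries. These correlations are across transcripts, which are not independent replicates. Brackish water library 1 had r of 0.845 and 0.864 with the fresh water libraries, and brackish water library 2 had r of 0.855 and 0.846 with the seawater libraries. Across these sets r was 0.608 and 0.80 for brackish water library 1 with seawater libraries 1 and 2, and 0.808 and 0.724 for brackish water library 2 with fresh water libraries 1 and 2. Of these, 0.80 and 0.808 were close to the 0.819 of the seawater pair. The first principal component held 64.0% of the variance, with brackish water library 1 at 113 and library 2 at -132.

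In the fit of all 6 libraries, fresh water against seawater gave more changed transcripts than either other pair, an order that did not hold without fresh water library 2 (12 calls against 24 and 14) or without brackish water library 1 (10463 against 13912 for fresh against brackish water). In fresh water 789 transcripts rose and 162 fell, 951 in all by limma with adjusted p under 0.05. The transcripts that rose were mostly of low abundance, with a median of 5.21 RPKM over the libraries and a median log2 fold change of 3.18. Low abundance was common to the tested transcripts. Of all 25901, 12819 lay at 1 to 3 RPKM and 7918 at 3 to 10 RPKM, against 200 and 388 of the 789 that rose. All 789 together, with 5 of a mean of at least 1000 RPKM among them, took 0.992% and 1.21% of the seawater reads and 10.3% and 8.25% of the fresh water reads. The transcripts that fell had a median of 50.9 RPKM and a median log2 fold change of -3.67, and went from 14.1% and 8.12% of the seawater reads to 4.02% and 0.666% of the fresh water reads. A large part of these shares, except in fresh water library 2, was 1 transcript, comp250031_c0_seq12. It held 1040541 and 1032448 reads in the seawater libraries and 756921 and 76 in the fresh water libraries.

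The transcript comp243666_c4_seq4 showed the largest rise in fresh water, from 18.2 ± 10.6 RPKM (SD, n = 2) in seawater to 3753 ± 1050 RPKM (SD, n = 2). Its log2 fold change was 7.70 with a standard error of 0.60 (limma adjusted p = 2.94e-08; 1.10e-54 to 0.312 over its 19 alternatives by limma, edgeR or DESeq2, 5 of which ended the call). The transcript comp236753_c0_seq1 rose from 1.84 ± 1.47 to 357 ± 101 RPKM, a log2 fold change of 7.05 with a standard error of 1.38 (limma adjusted p = 0.0112; 6.47e-10 to 0.312 over its 19 alternatives, 7 of which ended the call). In brackish water comp236753_c0_seq1 stood at 438 RPKM in library 1 and at 1.47 in library 2. The transcript comp242121_c3_seq1 fell from 594 ± 97.7 to 14 ± 18.7 RPKM, a log2 fold change of -6.38 with a standard error of 1.01 (limma adjusted p = 0.00217). Without fresh water library 2 its log2 fold change was -4.39 and it no longer passed (limma adjusted p = 0.0818; 3.38e-09 to 0.312 over its alternatives). The transcript comp250031_c0_seq12 had a log2 fold change of -6.58 (limma adjusted p = 0.0325), which rested on fresh water library 2. It stood at 11982 and 5921 RPKM in seawater, 4770 in fresh water library 1 and 0.623 in fresh water library 2. Without fresh water library 2 its log2 fold change was -0.82 (limma adjusted p = 0.826; 3.13e-87 to 0.826 over its alternatives). Summed over their components, the log2 fold change of comp243666_c4_seq4 was 6.26 and that of comp242121_c3_seq1 was -5.35.

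The scaling of the libraries bore on this comparison. The median log2 fold change of fresh water against seawater over all tested transcripts was 0.89 on RPKM and 0.08 with TMM factors, so rises on the RPKM scale are to be read relative to that shift. By abundance, the median on RPKM was 0.94 among transcripts of 1 to 3 RPKM and -0.28 among those of 100 RPKM or more, against 0.26 and -1.44 with TMM factors. Its sign turned among transcripts of 10 to 30 RPKM, from 0.76 to -0.31, and among those of 30 to 100 RPKM, from 0.21 to -0.91. All 951 called transcripts kept their sign with TMM factors, but this was fixed in advance. The factors were 0.655 and 0.874 in seawater and 1.55 and 1.87 in fresh water. They lower falls further and are too close to turn the smallest called rise, a log2 fold change of 1.73. With TMM factors limma called 0 (8405 at an unadjusted p under 0.05, of which 5038 were higher in fresh water). With TMM edgeR called 0 (14193), though it also recovered 0 of the changes simulated with the dispersions of the real libraries. The median log2 fold change of the 951 went from 3.18 to 2.39 for those that rose and from -3.67 to -4.58 for those that fell. Meanwhile the prior degrees of freedom of limma went from 22.8 to 2.55. With that lower prior, limma on RPKM also called 0 (4121 at an unadjusted p under 0.05), and with the higher prior limma with TMM factors called 8892, of which 60.9% were higher in fresh water. DESeq2 called 7738, of which 61.9% were higher in fresh water against 83.0% of the 951. The 951 calls became 289 without seawater library 1, 482 without seawater library 2, 10463 without brackish water library 1, 10305 without brackish water library 2, 125 without fresh water library 1 and 12 without fresh water library 2. The direction of the majority turned without seawater library 2, with 202 higher and 280 lower, and without fresh water library 1, with 53 higher and 72 lower. Without seawater library 2 and without fresh water library 1 the median log2 fold change over all tested transcripts stayed positive, at 1.06 and 0.99. With no filter beyond a non-zero value limma made 3 calls, 1 higher and 2 lower (60082 at an unadjusted p under 0.05, of which 58581 were higher).

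**Figure D2:**
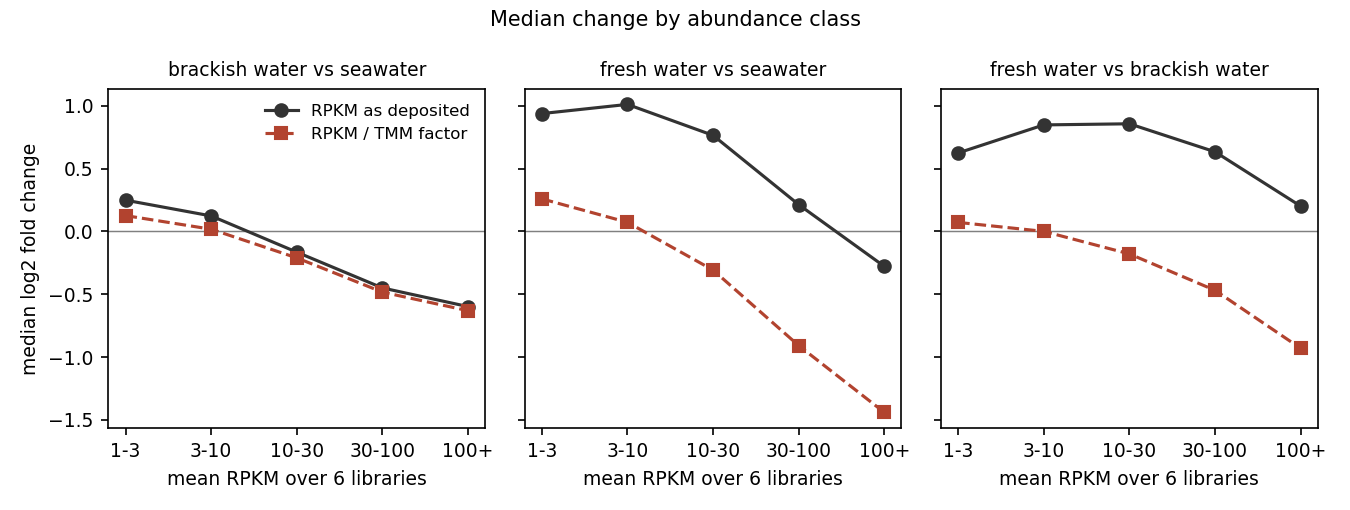
Median log2 fold change by mean RPKM class for the 3 pairs of groups, from RPKM as deposited (circles) and from RPKM divided by TMM factors (squares). For fresh water against seawater the median on RPKM goes from 0.94 in the class of 1 to 3 RPKM to -0.28 in the class of 100 RPKM or more.

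Brackish water against seawater gave few changed transcripts, and most of those that rose were abundant. In brackish water 18 transcripts from 12 components rose and 1 fell by limma. The 18 had a median of 1946 RPKM over the libraries, and 11 of them had a mean of at least 1000 RPKM. The lowest mean among the 18 was 5.17 RPKM. They took 1.80% and 1.64% of the seawater reads, 8.06% and 26.0% of the brackish water reads, and 2.04% and 1.03% of the fresh water reads. Abundant transcripts as a class did not rise. Of the 110 with a mean of at least 1000 RPKM, 30 had a positive log2 fold change in brackish water, and the median was -0.57.

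The transcript comp152470_c0_seq1 had 0 and 9.77 RPKM in seawater, 114 and 137 in brackish water, and 12.2 and 15 in fresh water. Its log2 fold change in brackish water was 5.27 with a standard error of 1.03 (limma adjusted p = 0.0363). Without seawater library 1 it was 3.55 and no longer passed. Without brackish water library 1 or 2 it no longer passed either, though it stayed at 5.40 and 5.13. Of its 19 alternatives, 11 ended the call. The transcript comp243666_c4_seq4 rose to 654 ± 161 RPKM (SD, n = 2), a log2 fold change of 5.19 with a standard error of 0.60 (limma adjusted p = 0.000118). Summed over the component of comp243666_c4_seq4 the log2 fold change was lower, at 3.45. The only transcript that fell was comp218213_c0_seq1, from 2756 ± 520 to 460 ± 90.1 RPKM, a log2 fold change of -2.58 with a standard error of 0.51 (limma adjusted p = 0.0363). For the last 2 transcripts the call was lost without brackish water library 1, though the log2 fold changes were 5.45 and -2.78. For comp218213_c0_seq1 it was also lost without brackish water library 2, at a log2 fold change of -2.38. Of 19 alternatives each, 8 ended the call of comp243666_c4_seq4 and 11 that of comp218213_c0_seq1.

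**Figure D3:**
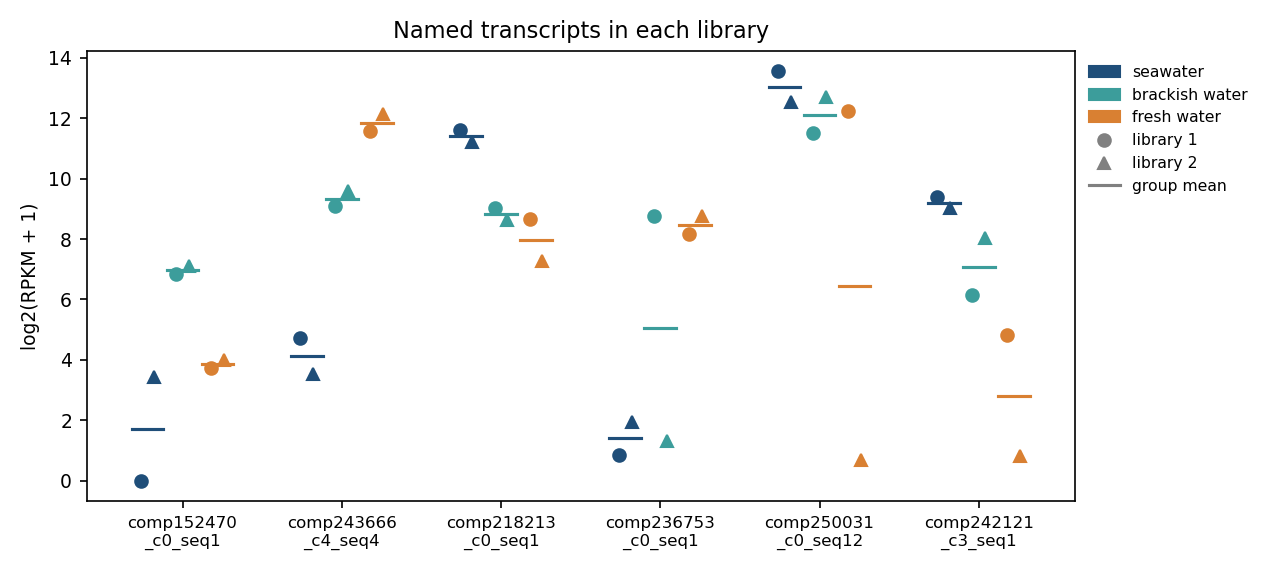
Levels of the named transcripts as log2(RPKM + 1) in each library, with circles for library 1, triangles for library 2 and bars for group means. The transcript comp243666_c4_seq4 lies higher in all brackish and fresh water libraries than in both seawater libraries, and comp236753_c0_seq1 differs between the brackish water libraries.

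The 19 calls of brackish water against seawater became 45 without seawater library 1, 450 without seawater library 2, 0 without brackish water library 1 (4250 at an unadjusted p under 0.05) and 5508 without brackish water library 2. Without seawater library 2 the direction of the majority turned, with 59 higher and 391 lower. With TMM factors limma called 0 (4970 at an unadjusted p under 0.05), edgeR with TMM called 0 (8672) and DESeq2 called 3493. The folds barely moved with TMM factors, with a median log2 fold change of 3.43 against 3.46 for the 18 and -2.62 against -2.58 for the 1 that fell. The factors of brackish water libraries 1 and 2, 1.54 and 0.391, lie on either side of the seawater factors, 0.655 and 0.874. They offset each other in the group mean but move the 2 libraries apart. Over 1 transcript for each of the 12 components, the median ratio of library 2 to library 1 went from 1.73 to 6.45. With the prior degrees of freedom exchanged between the fits, limma called 0 on RPKM (673 at an unadjusted p under 0.05) and 4287 with TMM factors, of which 79.3% were higher.

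Fresh water against brackish water gave 70 changed transcripts by limma, 41 higher and 29 lower in fresh water. The 29 that fell were mostly abundant, with a median of 1165 RPKM over the libraries. Of them 20 had a mean of at least 100 RPKM, while 7 lay at 3 to 10 RPKM. The 29 took 12.6% and 40.9% of the brackish water reads against 3.14% and 1.27% of the fresh water reads. The 41 that rose had a median of 6.34 RPKM. DESeq2 called 427, with 21.5% higher in fresh water against 58.6% of the 70, while limma with TMM factors called 0 (1539 at an unadjusted p under 0.05) and edgeR with TMM called 0 (3145). Median log2 fold changes with TMM factors were 2.85 against 3.59 for the 41 and -4.62 against -3.58 for the 29. With the prior degrees of freedom exchanged, limma called 0 on RPKM (712 at an unadjusted p under 0.05) and 851 with TMM factors, of which 46.5% were higher. The 70 calls became 282 without seawater library 1, 232 without seawater library 2, 13912 without brackish water library 1, 0 without brackish water library 2 (1400 at an unadjusted p under 0.05), 43 without fresh water library 1 and 14 without fresh water library 2. Most calls were lower in fresh water without fresh water library 1 (8 higher, 35 lower), without fresh water library 2 (2 higher, 12 lower) and with a pseudocount of 0.1 (6 higher, 21 lower).

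Among the 3 groups together, limma called 246 transcripts by its F test. This became 457 without seawater library 1, 808 without seawater library 2, 12136 without brackish water library 1, 7572 without brackish water library 2, 104 without fresh water library 1 and 35 without fresh water library 2. DESeq2 called 5270, and edgeR with TMM and limma with TMM factors called 0, with 10284 and 6245 at an unadjusted p under 0.05.

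Brackish and fresh water shared 3 called transcripts, 2 higher and 1 lower in both than in seawater, and 0 in opposite directions. The named transcripts among them were comp243666_c4_seq4 and comp218213_c0_seq1. Independent lists of these sizes would share 0.548 higher and 0.00625 lower. Simulated libraries of unchanged groups, with the same simulated seawater libraries in both comparisons, shared 0.08 on average. Unchanged groups are due few calls in either list, so 0.08 is no yardstick for lists of the sizes found. Across transcripts the log2 fold changes had r of 0.760 against a simulated mean of 0.50, and a covariance of 0.78 against 0.32, a difference of 0.46. The simulated noise was independent between transcripts, so shifts common to a whole library were left out. With 1 seawater library for each comparison, so that no control was shared, r was 0.257 and 0.406 and the covariance 0.38 and 0.49 for the 2 assignments. Calls were not recounted with the split controls, so part of the excess of shared calls may come from the shared controls. The 3 became 24 without seawater library 1, 153 without seawater library 2, 0 without brackish water library 1 and 5199 without brackish water library 2.

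The authors' deposited table of brackish water against seawater marked 3647 transcripts as significant, 2563 higher and 1084 lower. In the authors' deposited table of fresh water against seawater 54521 were marked, of which 97.9% were higher in fresh water. Under 10 reads on average in both groups lay behind 84.8% of the marks for brackish water and 80.0% of those for fresh water in the authors' deposited table. After Benjamini-Hochberg adjustment over the transcripts with a read, 278 and 3250 p-values of the authors' deposited table passed 0.05. The FDR columns of the authors' deposited table of all transcripts marked 348 transcripts for brackish water and 513 for fresh water against seawater, and 146 for fresh against brackish water. Of the transcripts called here by limma, 5 of 19 and 405 of 951 were also marked in the authors' deposited table.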

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

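The tests of detection breadth, the division of RPKM by TMM factors and the exchange of prior degrees of freedom were chosen only after the data were seen. The few-reads test was set before its result. Reads in transcripts below the mean of 1 RPKM, which the tests at the main filter left out, made up 3.29% of brackish water library 1, 3.60% of fresh water library 1 and 4.28% of fresh water library 2. These shares drew attention because they lay above both seawater libraries, at 1.06% and 1.18%, while brackish water library 2 was at 0.525%.

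Far more transcripts were detected in brackish water library 1 than in library 2. Depth was argued against, since the ratio stayed at 3.07 at equal depth. A few dominant transcripts were argued against as the whole cause, since the ratio was 2.56 without the 200 most abundant transcripts. If brackish water libraries are as broad as library 1, a swap with a seawater library needs a seawater library as broad as fresh water. Under that condition a swap of library 2 was argued against, since the highest seawater library reached 0.359 of the lowest fresh water library. If a brackish water library can be as narrow as library 2, that value cannot decide. A single wrong label or an outside sample stays open. Library 2 lay at 0.0321 on an axis from seawater (0) to fresh water (1), a position that a true brackish water library could also take. The left-out seawater libraries lay at 0.184 and 0.375. A wrong label on library 1 stays open as well: it lay at 0.869, with the left-out fresh water libraries at 0.754 and 1.19. Each left-out library was placed on an axis that ended, for its group, in the other library alone. The brackish water libraries were placed on the axis of both libraries of each group. These axes differ, so the order of the positions decides neither question. A response to salinity stays open and was untested.

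Most transcripts called in fresh water against seawater were higher in fresh water, 789 of 951. The majority of the calls turned without seawater library 2 and without fresh water library 1. In these 2 fits the median log2 fold change over all tested transcripts on RPKM stayed positive, at 1.06 and 0.99. With no filter beyond a non-zero value 1 call was higher and 2 were lower. At an unadjusted p under 0.05 by limma, 58581 of 60082 were higher with that filter. Scaling of the libraries stays open: with TMM factors limma called 0 transcripts (8405 at an unadjusted p under 0.05, 5038 of them higher; 0 by edgeR, 7738 by DESeq2), and these calls ended with lower prior degrees of freedom rather than lost folds, at a median log2 fold change of 2.39 against 3.18 for the risers. With the prior of the RPKM fit, limma with TMM factors called 8892, of which 60.9% were higher. This lies between the bounds of 60% and 75%, but these were set for the TMM fit without an exchanged prior. At an unadjusted p under 0.05 by limma, 6360 of 7077 were higher on RPKM and 3573 of 7427 with quantile normalization. Quantile normalization gives every library the same distribution of values, which by itself favours a balance of directions. Among the called transcripts with a mean of at least 100 reads, 432 of 572 or 75.5% were higher (Wilson 95% interval 71.8% to 78.9%). In this fit the majority was thus still present among transcripts of many reads. The share lies above the 60% below which few reads would have accounted for the pattern and near the 75% set beforehand for ruling few reads out. The interval takes transcripts of the same 6 libraries as independent, so it cannot show how far the share would move with other libraries. It therefore decides neither bound, and few reads are not ruled out. A response to fresh water stays open and was untested.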

How the results depend on the processing

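The counts of called transcripts changed under most alternatives, and values below are in the order brackish water against seawater, fresh water against seawater, fresh water against brackish water and the 3 groups. Limma with quantile normalization called 0, 0, 0 and 0 (4166, 7427, 2093 and 5629 at an unadjusted p under 0.05). With no filter beyond a non-zero value it called 0, 3, 0 and 0 (3558, 60082, 39460 and 37397 unadjusted), and with a mean RPKM of at least 5 it called 0, 1, 0 and 1 (488, 1629, 377 and 917 unadjusted). A pseudocount of 0.1 gave 6 for brackish water and 27 (6 higher, 21 lower) for fresh against brackish water, and 991 and 174 for the others. Fits of the compared groups alone gave 26, 10368 and 215. Sums per assembly component gave 48, 2094, 223 and 966.

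Chosen after seeing the data, limma on RPKM divided by TMM factors called 0 in each (4970, 8405, 1539 and 6245 unadjusted). The edgeR quasi-likelihood test with TMM, planned for deposited read counts, called 0 in each on the recovered reads (8672, 14193, 3145 and 10284 unadjusted). With DESeq2 size factors it also called 0 in each (8739, 14307, 3073 and 10343). In the simulation of fresh water against seawater with the dispersions of the real libraries, edgeR with TMM recovered 0 of 100 changes at either size. Its 0 calls in that comparison therefore cannot tell absent changes from missed ones. DESeq2 called 3493, 7738, 427 and 5270. The prior degrees of freedom were 22.8 in the limma fit of RPKM, 2.55 with TMM factors and 2.76 with quantile normalization. With the prior of the TMM fit, limma on RPKM called 0 in each (673, 4121, 712 and 1602 unadjusted), and with the prior of the RPKM fit, limma with TMM factors called 4287, 8892, 851 and 7968. The prior thus decided whether limma made calls with or without TMM factors. For the other alternatives the cause was not tested.

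The replicate block gave 39, 531, 125 and 393 calls and 9 shared calls against 3. Deviations of libraries of the same number correlated at -0.457 for seawater and brackish water, 0.266 for seawater and fresh water and -0.411 for brackish and fresh water, so the numbers were not taken to pair the samples.

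Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 0 to 5508, 12 to 10463, 0 to 13912 and 35 to 12136 calls, and 0 to 5199 shared calls. Of 133 alternatives for the named transcripts, 70 kept the direction and the side of the threshold, 63 kept the direction without passing it and 0 reversed. The named transcripts were chosen for large folds between groups that did not overlap. Their direction could not turn when a library was left out or with another pseudocount. Other filters, the replicate block, fits of the compared groups alone and exchanged priors leave the fold unchanged. The 0 reversed is therefore no measure of how firm the directions are. The mean position of the brackish water libraries between seawater (0) and fresh water (1) was 0.450, a mean of 0.869 in library 1 and 0.0321 in library 2, and 0.580, 0.487 and 0.438 with TMM factors, a pseudocount of 0.1 and a mean RPKM of at least 5. Tests of the gene lists and their alternatives were not run, because the IDs matched no gene name.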

Other observations

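The tests of a common RNA source and of its scaling were chosen after the result was seen, and the test of transcript usage was set before it, with its sensitivity measured afterwards. Transcripts with reads in exactly 2 of the 6 libraries were counted for all 15 pairs. The fresh water pair held 37901, the most of any pair, and the pairs of brackish water library 1 with fresh water libraries 1 and 2 held 23652 and 20631. The seawater pair held 455 and the brackish water pair 1737. Few were well covered: 83 of the 37901 had at least 10 reads in both fresh water libraries, and their median was 5 reads in the pair.

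Detection from all reads, at unequal depth, differed between libraries among transcripts of up to 1000 bases and little among those above 2000 bases. Of transcripts of 201 to 300 bases, 4.32% and 7.74% had a read in the seawater libraries, 48.5% and 5.23% in the brackish water libraries, and 49.3% and 52.4% in the fresh water libraries. Of those of more than 300 and up to 500 bases, the shares were 15.6% and 24.4%, 71.7% and 18.5%, and 73.9% and 73.5% in the same order. Of those of more than 500 and up to 1000 bases, they were 60.1% and 73.1%, 95.6% and 67.6%, and 95.4% and 94.8%. Of those above 2000 bases, the libraries detected 99.6% to 99.98%, which leaves little room for a difference. The 110 transcripts with a mean of at least 1000 RPKM took 58.9% of the reads of brackish water library 2, against 19.2% to 32.1% in the other libraries.

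Whether transcripts of one component changed in opposite proportions was tested with limma diffSplice over 3654 components with several tested transcripts. For fresh water against seawater 5 components, or 0.137%, were called, with 150 at an unadjusted p under 0.05. For brackish water against seawater and fresh against brackish water 0 were called, with 76 and 39. The 0.137% lies under the 1% set beforehand, but that bound was too high for changes of moderate size. With 1 transcript raised 4-fold and another lowered 4-fold in the fresh water values of 5% of the components, diffSplice called 0.219% to 0.684% of all components over 20 draws and recovered 4.40% of the changed ones on average. With 16-fold changes each way it called 5.12% to 5.50%, far above the 0.137% found, so changes that large in 5% of the components would have been seen. Smaller changes, or changes in fewer components, stay open.

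The transcripts called higher in brackish water took about 3 times the share of reads in library 2 as in library 1, 26.0% against 8.06%. A ratio of about 3 was therefore supposed for each transcript, and this was wrong: over 1 transcript for each of the 12 components, the median ratio of RPKM + 1 was 1.73, from 0.386 to 3.32. A common source of RNA would give one ratio, and the SD of the log2 ratio was 0.90, at percentile 7.23 among 10000 sets matched on mean RPKM, whose median SD was 1.43. The matched sets came from transcripts that were not called, while a call favours small differences between the libraries of a group. The low percentile may come from that choice and does not speak for a common source. A common source stays possible but undecided, since the SD was neither under the 0.5 that it would need nor as wide as the median of the matched sets. The median ratio was 6.45 when RPKM was divided by TMM factors before 1 was added. These factors multiply every ratio of RPKM itself by the same amount, so this value decides nothing about scaling.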
